A study of Homo sapiens with 5 samples.

How the data were processed

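Total RNA from 1 pool of vastus lateralis muscle biopsies, the pool that the labels number 3 and call insulin resistant, was hybridised to 5 oligonucleotide arrays. The arrays were HuFL and the 4 members of the Hu35K set, subA, subB, subC and subD, with 1 hybridisation on each. The labels give no comparison group, no number of donors in the pool and no repeat hybridisation, so no difference between conditions could be tested and no p-value is given.

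Each array's deposited table holds 1 whole number per probe set, a linear intensity that can lie below 0. The software, background handling and scaling that gave these intensities are not given in the sources used here. Between 25.8% and 40.9% of the values on an array lay below 0, a property of signals from which another signal has been subtracted. No upstream step beyond that was assumed. The medians differed between arrays, from 19.0 on Hu35K subB to 85.0 on Hu35K subA, so intensities were compared within an array and genes were set side by side across arrays only as ranks. Probe sets respond differently to the same amount of RNA, so neither intensities nor ranks order transcripts by abundance.

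Probe sets whose identifiers mark them as manufacturer's controls, 58 on each array, were kept apart. This left 7071 probe sets on HuFL, 8876 on Hu35K subA, 8866 on subB, 8870 on subC and 8870 on subD, 42553 in all. Gene names came from GEO's platform annotation, with symbols updated by Entrez identifier through a RefSeq gene table of the assembly GRCh38.p14. No symbol changed in that step, and 75 named probe sets had no match in the RefSeq table and kept their annotated symbol. Of the 42553 probe sets, 29711 had 1 gene symbol, 857 had several and 11985 had none in that table. Those with several or none were counted as probe sets and were not used for genes. The 29711 probe sets stood for 14746 genes. A small set of genes that bear on a person's identity was left out of the gene analysis, which left 14711. The arrays name no genome build, so no coordinates are given.

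The noise SD of an array was the root mean square of its values below 0 over the probe sets that were not controls, and a probe set above 3 noise SD was counted as above the limit. Counts of probe sets or genes are given with exact binomial (Clopper-Pearson) intervals at 95%, which cover counting error only. The number of arrays, 1 of each type, limits the precision. The alternatives were limits at 2 and 5 noise SD and at the highest of the 15 control probe sets for Bacillus subtilis genes, whose transcripts the labels do not say were added. A robust limit, 3 times the median size of the values below 0 scaled to an SD, was added after seeing the data, because extreme values below 0 enlarged the noise SD. On HuFL the noise SD was 1045.0 over 2108 values below 0, and most of its sum of squares came from 1 probe set at -38641. The HuFL limit, and which genes lie under it, therefore depend strongly on that probe set.

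For gene lists, each gene was given the median over its probe sets of the percentile rank within the array, from 0 for the dimmest probe set to 100 for the brightest. The median of each of 27 lists fixed before the data were examined was set against 10000 random lists of as many genes, matched on the number of probe sets per gene (1, 2, 3, or 4 or more) and on presence on HuFL. A list was called above its random lists when its median exceeded 95% of theirs. These percentiles describe these 5 hybridisations and are not p-values. Of the 27 lists, 3 hold genes known from liver, from pancreas and gut, and from testis, eye and skin, and served as background. List symbols that the annotation does not hold were looked up as older symbols, only where the symbol is no other gene's present name and a single measured gene carries it. The alternatives were the highest probe set per gene, ranks over all arrays together, HuFL alone, the Hu35K arrays alone, probe sets without the suffixes that mark shared or relaxed probe choices, and genes above the limit alone. Probe sets listed at exactly 0 on HuFL were also treated as not measured, an alternative chosen after seeing the data.

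Agreement between array types was the Spearman correlation across genes between the rank on HuFL and the rank on the Hu35K arrays, with an interval from 1000 bootstrap resamples of genes. Genes are not independent replicates. The spread of control probe sets above the limit on all 5 arrays was given as the coefficient of variation (CV) over the arrays. This CV holds differences in scale and array type besides repeat error. One alternative divided each array by its mean after removal of the highest and lowest 2% of values. The others raised the limit or left out each array in turn.

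The genes named were fixed by rule before the data were examined. They were the 4 genes with the highest value on each array, the 3 highest-ranked genes of each list, 18 genes of insulin action, fuel use and fibre type, and the 3 genes above the limit on either array type whose ranks differed most between HuFL and Hu35K. For the highest values, the arrays were taken from HuFL to Hu35K subD, and a gene already taken was passed over for the next. All other genes named, whether or not the text says so again where they appear, were chosen after their values were seen.

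The steps were tested on simulated data of 42553 probe sets. The noise SD came out at 201.2 where 200.0 had been simulated, 0.11% of unexpressed probe sets passed the limit, and 99.9% of those simulated above 1000 did. The simulated noise was normal with the same SD on every array. It could therefore not show how extreme values below 0 enlarge the limit, which in the data stood at 3135 on HuFL. A raised list of 20 genes reached the percentile 100.0. Of 100 unshifted lists, 12 passed the 95 mark, more than the 5% aimed at. A draw of 1000 unshifted lists, added after that count was seen, gave 40, or 4.0%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.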

Results

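The RNA of a single pool of insulin-resistant human muscle, taken from the vastus lateralis of the thigh, was measured on 5 arrays. Together the arrays carry 42553 probe sets, of which 29711 stand for 14746 named genes. HuFL carries mostly characterised genes, and the 4 Hu35K arrays carry mostly expressed sequence tags. With 1 pool and 1 hybridisation per array, the values describe this pool, and no contrast with insulin-sensitive muscle was analysed here. The median intensity was 35.0 on HuFL, 85.0 on Hu35K subA, 19.0 on subB, 26.0 on subC and 41.0 on subD.

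On HuFL the highest value, 32025, belonged to ATP2A1, the calcium pump of the fast-fibre sarcoplasmic reticulum. It was followed by MYBPC2, the fast-type myosin-binding protein C, at 29567, TNNT1, slow troponin T, at 26422, and MYH2, the fast IIa myosin heavy chain, at 25108. On Hu35K subA the highest genes were RPS27, a ribosomal protein, at 13888, NDRG2 at 12497, MYL1, a fast myosin light chain, at 12145, and TMOD4, which caps thin filaments, at 11773. Hu35K subB was led by MYOZ1, a Z-disc protein, at 8271, the small heat shock protein HSPB7 at 7094, the mitochondrial protein CHCHD10 at 6316 and TMEM176A at 4342.

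On Hu35K subC the leading genes were CMYA5, a cardiac and skeletal muscle protein also called myospryn, at 20236 and the ribosomal protein RPS15 at 15242. The next leading genes there were the glycolytic enzyme GAPDH at 15222, TNNT1, already named for HuFL, at 12171 and the haemoglobin alpha gene HBA2 at 11483. On Hu35K subD they were the small heat shock protein HSPB1 at 16566, the PDZ and LIM protein PDLIM7 at 14169, a further small heat shock protein, HSPB6, at 13698, and TXNIP, an inhibitor of thioredoxin and of glucose uptake, at 12856. Several of these genes also had dim probe sets. RPS15 read -101 on a second Hu35K subC probe set, PDLIM7 read -67 on another Hu35K subD probe set and 152 on HuFL, and HSPB6 read -417 on one Hu35K subD probe set and 2592 on another.

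The number of probe sets above 3 noise SD was 206 of 7071 on HuFL (2.91%, exact 95% interval 2.53 to 3.33). It was 482 on Hu35K subA (5.43%, 4.97 to 5.92), 226 on subB (2.55%, 2.23 to 2.90), 287 on subC (3.24%, 2.88 to 3.63) and 404 on subD (4.55%, 4.13 to 5.01). The limit stood at 3135 on HuFL, where 1 probe set at -38641 enlarged it, and between 551.5 and 1134 on the Hu35K arrays. A robust limit, chosen after seeing the data, gave 881, 1832, 681, 1191 and 1590 probe sets in the same order. Of the 14711 genes analysed, 1126 had a probe set above 3 noise SD (7.7%) and 3938 had one above the robust limit (26.8%). On HuFL 1054 probe sets (14.9%) were listed at exactly 0, among them probe sets for the skeletal actin ACTA1, the giant sarcomere protein TTN and the elongation factor EEF2, so a 0 there is given only as listed at 0. In the lists below, a gene with only such probe sets counts as not above the limit.

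**Figure D1:**
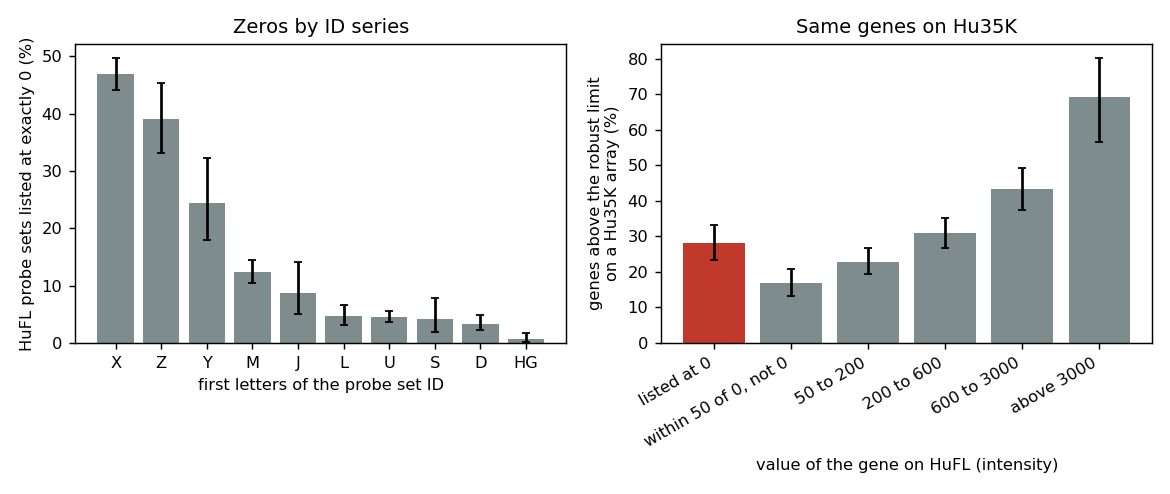
Left, percent of HuFL probe sets listed at exactly 0 by the first letters of the probe set identifier, from 46.9% for X to 0.6% for HG; right, percent of genes above the robust limit on a Hu35K array, by their value on HuFL (intensity), with exact 95% intervals as error bars. Genes listed at 0 on HuFL were above that limit in 28.0% of cases, against 16.8% of those within 50 of 0 and 69.2% of those in the highest class of HuFL values.

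Contractile and structural muscle genes were bright. Of 20 measured genes of the thick and thin filaments, 15 were above the limit and the median percentile was 99.1 (95% interval 92.7 to 99.9), against 50.4 for matched random lists. TNNT1 and MYH2 led it, with TNNC2, fast troponin C, at 24431 on HuFL. The Z disc, M band and costamere list had 11 of 16 genes above the limit and a median of 95.3. MYOZ1 was joined at its top by TCAP, which anchors titin at the Z disc, at 8811 on Hu35K subD and by CRYAB, a chaperone of desmin, at 14310 on HuFL. Both medians exceeded 100% of their random lists.

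Fast and slow fibre genes were both bright. In the fast list 11 of 12 genes were above the limit (median 99.7), and in the slow list 7 of 11 were (median 92.7). The fast list held ATP2A1, MYH2 and TNNC2 at its top, with MYH1, the IIx heavy chain, at 7665 on Hu35K subD, and its gene under the limit was parvalbumin (PVALB). The slow list held TNNT1, the oxygen store myoglobin (MB) at 23187 and slow troponin C (TNNC1) at 22352 on HuFL. MYH7, the slow heavy chain, read 16882 on one HuFL probe set and was listed at 0 on another. MYL2 and CA3, 2 of the slow genes, were measured only by probe sets listed at 0, against 0 of the fast genes, and different probe sets give no ratio of fast to slow fibres. Other lists held 11 of the fast and 8 of the slow genes, and both medians exceeded 100% of their random lists. Among genes above the limit alone, the slow list stood at 74.1 among its random lists.

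Excitation and calcium handling genes had 7 of 16 members above the limit and a median of 93.9. After ATP2A1 came CASQ1, the calcium store of the fast reticulum, at 8262 on Hu35K subC and sarcolipin (SLN), a regulator of the calcium pump, at 20886 on HuFL. Of the 8 genes of the creatine and adenylate buffer, 4 were above the limit, with a median of 91.2. They were GAMT, which completes creatine synthesis, at 14859, the mitochondrial creatine kinase CKMT2 at 3273 and the muscle AMP deaminase AMPD1 at 5387, all on HuFL, and the brain-type creatine kinase CKB at 1468 on Hu35K subD. All CKB probe sets were suffixed, and those not above the limit read 950 on subD and -1568 on HuFL. Without suffixed probe sets, 3 of 7 genes of the creatine list were above the limit. Both lists exceeded 100% of their random lists. CKM, the main muscle creatine kinase, was listed at 0 on its HuFL probe set. With genes above the limit alone the creatine list stood at 74.6.

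**Figure D2:**
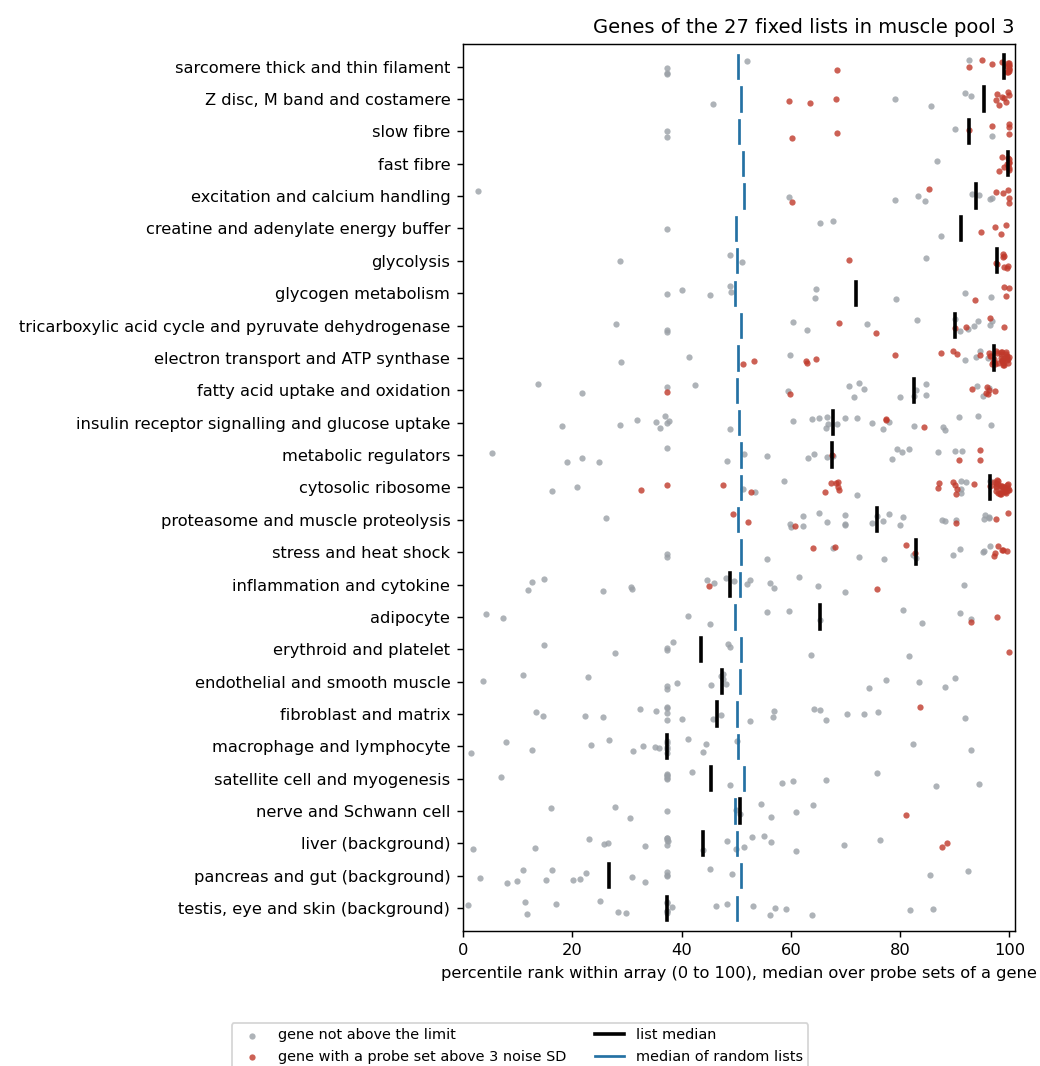
Each point is 1 gene of the 27 fixed lists, placed by its percentile rank within the array (0 to 100, median over its probe sets); red points have a probe set above 3 noise SD, the black bar is the list median and the blue bar the median of matched random lists. The fast fibre list has its median at 99.7 and the pancreas and gut list at 26.8, and the points stacked at 37.3 are mostly genes listed at 0 on HuFL.

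Genes of oxidative phosphorylation and glycolysis stood near the top of their arrays. Of 46 genes of electron transport and ATP synthase, 39 were above the limit (84.8%, exact interval 71.1 to 93.7) and the median percentile was 97.1. COX7A1, the muscle form of a cytochrome oxidase subunit, read 22098 on HuFL, and the complex I subunit NDUFA1 read 11002 and the ATP synthase subunit ATP5ME 7096 on Hu35K subA. Glycolysis had 9 of 13 genes above the limit and a median of 97.7. GAPDH read 19541 on HuFL, where the aldolase ALDOA read 17539 and the muscle enolase ENO3 read 11588. HK2, the insulin-responsive hexokinase, read -205 on HuFL, 9 on Hu35K subA and 55 on subC, all below the limits. Both lists exceeded 100% of their random lists.

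The tricarboxylic acid cycle and pyruvate dehydrogenase list had 6 of 20 genes above the limit and a median of 90.1. MDH2, mitochondrial malate dehydrogenase, read 6241 on Hu35K subD. SDHA of complex II and PDHA1 of pyruvate dehydrogenase read 2789 and 2541 on HuFL, under its limit but above the robust limit. PDK4, the kinase that shuts off pyruvate dehydrogenase in fasting, read 973 on Hu35K subA, 114 on HuFL and -6 on subB. Fatty acid uptake and oxidation had 8 of 25 genes above the limit and a median of 82.6. Without suffixed probe sets, 2 of 22 genes of that list were above it. The fatty acid transporter CD36 read 6362 and 1017 on its HuFL probe sets, and the enoyl-CoA hydratase ECHS1 read 3446 there. The isomerase ECI1 read 3740 on Hu35K subA and the muscle fatty acid carrier FABP3 read 2338 on HuFL, under its limit but above the robust limit. LPL, which releases fatty acids from lipoproteins, read 227, and the uncoupling protein UCP3 read 821 on Hu35K subD and 252 and 72 on HuFL. Both lists exceeded 100% of their random lists, and stood at 78.4 and 86.2 among genes above the limit alone.

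Glycogen metabolism was led by PPP1R3C, a glycogen-targeting phosphatase subunit, at 3230 on Hu35K subB. Phosphoglucomutase (PGM1) followed at 13874 on HuFL, and the muscle glycogen phosphorylase PYGM read 10415 on Hu35K subD and 6688 on HuFL. With the branching enzyme GBE1 at 1744 on Hu35K subD, 4 of the 14 genes were above the limit. The median of 72.0 exceeded 99.3% of random lists. That standing was lost with HuFL alone (93.4) and with the Hu35K arrays alone (82.7).

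Genes of insulin signalling passed the limit about as rarely as all genes. Of 30, 3 were above the limit (10%, exact interval 2.1 to 26.5), against 7.7% of all genes. Above the robust limit were 13 (43.3%), against 26.8% of all genes. The 3 above the limit, named because their values were seen, included the transcription factor FOXO3 at 1236 and the kinase PRKCQ at 1422 on Hu35K subA. The last was the phosphatase PTPN1 at 553 on subB, just above the limit of 551.5 there. The median percentile of all 30 genes, 67.7 (60.4 to 77.5), exceeded 99.9% of random lists. Glycogen synthase (GYS1) read 2644 on HuFL, TBC1D4, an AKT substrate that governs glucose transporter traffic, read 1079 on Hu35K subA, and the insulin-responsive transporter SLC2A4 read 1639 and 539 on HuFL and 778 on Hu35K subA. None of these values passed its array's limit, and all but the 539 passed the robust limit. When each gene was given its highest probe set, the list median was 80.7, against 77.4 for matched random lists, a standing of 77.7. Among genes above the limit alone, 3 genes, the list stood at 69.4.

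No probe set for the insulin receptor or its substrates was above the limit. INSR had 7 probe sets, from -201 on Hu35K subD to 374 on the same array, and IRS1 had 6, from -138 on Hu35K subC to 311 on subA. IRS2 read 221 on Hu35K subA and -188 on subC. PIK3R1, the regulatory subunit of phosphoinositide 3-kinase, read 2, -8 and -10 on HuFL, subB and subC. AKT2, the kinase downstream of it, read between 155 on Hu35K subA and 376 on subC. At the robust limit INSR and AKT2 each had a probe set above it, and IRS1, IRS2 and PIK3R1 had none, which does not show that they were absent.

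Metabolic regulators had 4 of 23 genes above the limit and a median of 67.5, above 99.1% of random lists. The muscle transcription factor MEF2D read 2110 on Hu35K subB and 1952 on subA, but 654 on subD and 0 on subC, under their limits. The retinoid receptor RXRA read 1563 on Hu35K subD, 801 on subC, 357 on subB and -10 on subA, and was listed at 0 on HuFL. PRKAG3, the muscle gamma subunit of AMP-activated kinase, read 331 on Hu35K subC, under its limit but above the robust limit. PPARGC1A, a coactivator of mitochondrial genes, read 1491 and 53 on Hu35K subD and 75 on subC. It passed the limit only through the 1491, which came from a suffixed probe set. Without suffixed probe sets, 2 of 22 metabolic regulators were above the limit. MEF2C, a relative of MEF2D and named after its value was seen, read 4802 on Hu35K subD. With HuFL alone the list stood at 64.9.

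Ribosomal protein genes were bright, with 44 of 55 above the limit (80.0%, exact interval 67.0 to 89.6) and a median of 96.4. RPL30 read 11432 on Hu35K subD, RPL4 read 6818 on subC and RPL32 read 18230 on HuFL. Processed pseudogenes resemble many of these genes, and whether the probe sets tell the copies apart was not tested. Stress and heat shock genes had 10 of 23 above the limit and a median of 83.0, led by HSPB1, HSPB6 and HSPB7. Without suffixed probe sets, 5 of 22 stress genes were above the limit. Proteasome and muscle proteolysis genes had 6 of 29 above it and a median of 75.7, with ubiquitin B (UBB) at 19234 and the catalytic subunit PSMB6 at 4208 on HuFL. The ATPase PSMC3 read 2408 on HuFL, under the limit but above the robust limit. All 3 lists exceeded 100% of their random lists. Among genes above the limit alone the ribosome list stood at 75.1 and the proteasome list at 3.2, and with the Hu35K arrays alone the proteasome list stood at 87.3.

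Inflammation genes were not bright as a group. Of 20, 2 were above the limit, and the median of 48.8 exceeded 39.8% of random lists. NFKBIA, the inhibitor of NF-kappa-B, read 1056 on HuFL, its kinase IKBKB read 745 and 26 on Hu35K subB, and the chemokine CCL2 read 217 on HuFL. The second gene above the limit, named after its value was seen, was the receptor subunit IL6ST at 744 on Hu35K subB.

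Markers of other cell types in muscle were mostly below the limit, which 7.7% of all genes passed. The shares of all genes given here were not matched to the lists on probe sets per gene. The robust limit was passed by 26.8% of all genes and by 6 of 13 adipocyte genes. It was passed by 4 of 10 erythroid and platelet, 4 of 16 endothelial and smooth muscle, and 7 of 24 fibroblast and matrix genes. It was also passed by 2 of 20 macrophage and lymphocyte, 4 of 14 satellite cell and myogenesis, and 3 of 11 nerve and Schwann cell genes. Adipocyte genes had 2 of 13 above 3 noise SD, GPD1 at 2038 and complement factor D (CFD) at 2348, both on Hu35K subA. CFD also read 1193 on HuFL, under its limit, and -225 on another Hu35K subA probe set. The adipocyte list's median of 65.4 exceeded 93.0% of random lists, and 100% when suffixed probe sets were left out. FABP4, the fat cell fatty acid carrier, read 1182 on HuFL, and 2 of the adipocyte genes, GPD1 and PPARG, also stand in a muscle list. Erythroid and platelet genes had 1 of 10 above the limit, HBA2, and 2 of the 10 were listed at 0 only. The haem enzyme ALAS2 read up to 448 on HuFL and the red cell carbonic anhydrase CA1 read 297 on Hu35K subC. The list exceeded 27% of random lists, or 98.9% with the 4 of its genes on the Hu35K arrays alone. The only HBA2 probe set was suffixed. Without suffixed probe sets, 0 of 9 genes of the list passed either limit and the list exceeded 16.0% of random lists.

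Endothelial and smooth muscle genes had 0 of 16 above the limit (exact upper bound 20.6%) and exceeded 35.9% of random lists. ACTA2 and CDH5, 2 of the 16, were listed at 0 only. SMTN read 1018, CAV1 740 and the vascular growth factor receptor FLT1 up to 524 on HuFL. Fibroblast and matrix genes had 1 of 24 above it, TIMP2 at 649 on Hu35K subB, and exceeded 27.9% of random lists. COL1A1, TIMP1 and VIM, 3 of the 24, were listed at 0 only, and with zeros on HuFL treated as not measured the 21 genes left exceeded 69.9%. The basement membrane collagen COL4A1 read 1109 and lumican (LUM) 313 on HuFL. Macrophage and lymphocyte genes had 0 of 20 above the limit (upper bound 16.8%) and a median of 37.3, which exceeded 3.7% of random lists. CD163, CSF1R and S100A8, 3 of the 20, were listed at 0 only, and 37.3 is also the rank that the zeros on HuFL share. Their highest-ranked genes were CD3E at 1194 on HuFL, lysozyme (LYZ) at up to 1545 and the leukocyte phosphatase PTPRC at up to 27.

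Satellite cell and myogenesis genes had 0 of 14 above the limit (upper bound 23.2%) and exceeded 28.4% of random lists. MYF6, MYH8, MYOD1 and MYOG, 4 of the 14, were listed at 0 only, and with zeros on HuFL treated as not measured the 10 genes left exceeded 70.3%. The growth factor IGF2 read 872 on Hu35K subD, the cadherin CDH15 read 649 and the adhesion molecule NCAM1 read up to 546 on HuFL. Myostatin (MSTN), which restrains muscle growth, read 70 on Hu35K subC. Nerve and Schwann cell genes had 1 of 11 above the limit, the myelin gene MAG at 1174 on Hu35K subC, and exceeded 53.8% of random lists. MAG also read 440 on HuFL and 185 on Hu35K subA, under their limits. Only its suffixed probe set passed, and without suffixed probe sets 0 of 10 genes of the list did. STMN2 and the neurofilament gene NEFH read 143 and 84 on HuFL.

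The 3 background lists gave the level of genes not known from muscle. Of their 63 genes, 2 were above the limit (3.2%, exact interval 0.4 to 11), the liver genes APOC3 at 1394 on Hu35K subD and F2 at 777 on subB. Of the 63, 10 were listed at 0 only. Liver genes exceeded 17.7% of random lists, with FGG at 324 on HuFL. Pancreas and gut genes exceeded 0.4%, with somatostatin (SST) at 1147, MUC2 at 605 and PGC at 30 on HuFL. Testis, eye and skin genes exceeded 3.8%, with KRT14 at 622 and KRT1 at 487 on HuFL and CRYAA at 573 on Hu35K subD. With zeros on HuFL treated as not measured, liver genes exceeded 41.4% and testis, eye and skin genes 18.5% of random lists. In that setting the erythroid and platelet list exceeded 45.8%, the endothelial and smooth muscle list 23.3%, the macrophage and lymphocyte list 1.3% and the inflammation list 25.1%. In all, 16 of the 27 lists were above their random lists, all of them among the 24 that were not background.

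The same genes could be ranked on both array types in 2846 cases, which tests how well the arrays ranked a gene alike within this pool, by different probe sets or by the same. HuFL and Hu35K subA shared 466 probe set identifiers. PSMD8, a proteasome subunit, read 5426 on HuFL and -1003 on Hu35K subA. The brain-type creatine kinase CKB read -1568 on HuFL but 1468 and 950 on Hu35K subD, and ATP5MC1, a subunit of ATP synthase, read 4462 on HuFL and -212 on subC. Of 65 genes above the limit on HuFL, 35 were above it on a Hu35K array (53.8%, exact interval 41.0 to 66.3), against 180 of the other 2781 (6.5%, 5.6 to 7.5). The rank correlation across genes was 0.17 (bootstrap interval 0.13 to 0.21), and 0.46 over the 35 genes above the limit on both. It was 0.11 without suffixed probe sets.

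Control probe sets for human transcripts, shared by the 5 arrays, measured the same pool on every array. The 5' probe set of GAPDH averaged 18474 ± 6817 (SD, n = 5 arrays), that of beta-actin 8410 ± 2877, and that of a small-subunit ribosomal RNA control 3581 ± 1294. Among 10 control probe sets above the limit on every array, the median CV was 38.2% (interval 34.2 to 57.0). The 7 for human transcripts had a median CV of 36.1% and the 3 for added bacterial and phage transcripts 57.0%. The bacteriophage Cre control CreX-5 varied most, from 1744 on Hu35K subC to 11749 on subD, a CV of 61.2%. Dividing each array by its trimmed mean raised the median CV to 51.9%.

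**Figure D3:**
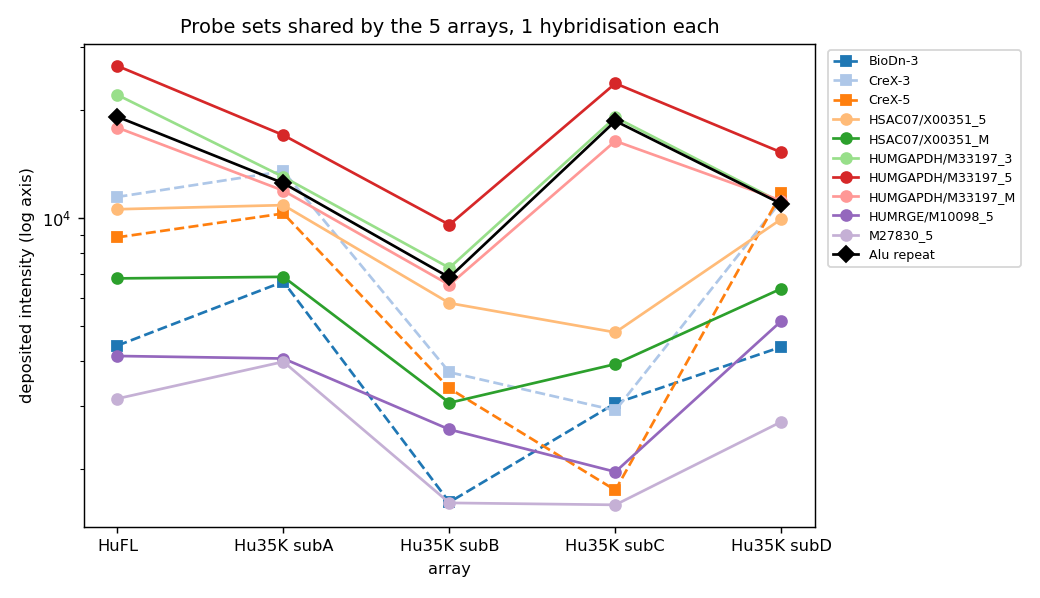
Deposited intensity (log axis) of the 10 control probe sets above the limit on all 5 arrays and of the Alu repeat probe set, 1 hybridisation per array; circles are human transcripts, squares are added spikes and diamonds the Alu repeat. GAPDH probe sets were higher on Hu35K subC than on subD while CreX-5 fell from 11749 on subD to 1744 on subC.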

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

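All tests in this part were chosen after the results they measure were seen. No group of 4 or more samples and no contrast in several groups exists here, so only signals outside the main measurement were looked for. No biological explanation was tested, since the labels give 1 group.

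Of the antisense control probe sets, only that for the 3' end of beta-actin lay above the highest Bacillus control on every array, from 461 on Hu35K subB to 1053 on HuFL. On all 5 arrays it lay under 3 noise SD (551.5 on Hu35K subB and 3135 on HuFL) and above the robust limit (275.8 and 702.8). Such signal was not confined to it. The antisense probe set for the 3' end of GAPDH passed the highest Bacillus control on 4 arrays, at 293 to 440, that for the middle of GAPDH on 2, at 279 and 533, and that for the middle of beta-actin on Hu35K subB, subC and subD (-116 to 365 over the 5 arrays). An antisense probe set for the bacterial spike BioB read 839 on Hu35K subD, and the one for the 5' end of beta-actin read from -362 to -157. The probe set for the Alu repeat, an element spread through introns and untranslated regions, was among the brightest on every array, from 6842 on Hu35K subB to 19205 on HuFL (13649 ± 5268, SD, n = 5 arrays).

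Human controls moved apart between Hu35K subC and subD. Among the 10 human control probe sets above 3 noise SD on subB, subC and subD, the 3 for GAPDH were 1.47 to 1.73 times as bright on subC as on subD, and the 7 for ribosomal RNA and beta-actin 0.29 to 0.68 times, a spread of 5.9 times that a single scale factor per array could not give. A scanner ceiling on subC would lower the ratios of GAPDH, the brightest, below those of the dimmer controls, and the lowest GAPDH ratio was 2.17 times the highest of theirs, which argues against it. A ceiling on subD alone would leave the ratios of subC to subB together, but these were 2.48 to 2.63 for GAPDH and 0.49 to 1.28 for the others, the lowest of the former 1.93 times the highest of the latter. What moved the controls apart stays open.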

How the results depend on the processing

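The robust limit, the treatment of zeros as not measured and the comparison of identical probe set identifiers with zeros left out were chosen after seeing the data; the other alternatives were fixed before. Counts of probe sets above the limit depended on the limit. On HuFL, Hu35K subA, subB, subC and subD, the Bacillus limit gave 1739, 2306, 2047, 2437 and 3126, and the robust limit 881, 1832, 681, 1191 and 1590. On the Hu35K arrays in the same order, 2 noise SD gave 855, 450, 477 and 668, and 5 noise SD gave 235, 105, 130 and 210. Signal over background therefore limits which dim genes can be called, and the order of arrays by count was not the same under all limits.

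Over all alternatives, 164 of 178 standings of single lists kept their side of the 95 mark, 12 lost it and 2 gained it. Of the 16 lists above the mark, 12 kept it in every alternative other than the restriction to genes above the limit, and 7 kept it there too. That restriction left 16 lists with at least 3 genes, of which 9 were above the mark; it compares bright genes with bright genes, by its own construction. The other alternatives gave 14 to 17 lists, and 16 when zeros on HuFL were treated as not measured. Counts of genes above the limit depended on suffixed probe sets in several lists. Without them, 8 of 14 thick and thin filament genes, 4 of 9 slow fibre genes and 5 of 11 glycolysis genes were above it. The Z disc, M band and costamere list kept 11 of 16.

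The correlation between array types was 0.46 among genes above the limit on both, 0.11 without suffixed probe sets and 0.20 with zeros on HuFL treated as not measured. It was 0.34 with both the zeros left out and the comparison limited to identical probe set identifiers on HuFL and Hu35K subA, 405 of the 466 shared; the cause was not tested. The median CV of controls was 32.0% without Hu35K subB, against 38.2% on all arrays, and 40.3% to 42.1% without one of the others. No paired analysis was possible because the series holds 1 pool with 1 array of each type.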

Other observations

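Genes outside the fixed lists that were also bright are given here as values, chosen after the values were seen. ADSS1, the muscle adenylosuccinate synthase of the purine nucleotide cycle, read 7047 on Hu35K subA and 9270 on subD. KLHL41, a sarcomere-associated kelch protein, read 6598 on subA and 7817 on subD. ANKRD23, a titin-binding ankyrin repeat protein, read 9357 on Hu35K subC. EEF1A2, the elongation factor form of muscle and nerve, read 14039 on HuFL, and RPL3L, the muscle form of a ribosomal protein, read 9223. TPT1, an abundant translation-related transcript, read 24194 on HuFL and 1257 on Hu35K subB. APOD, a lipid carrier of connective tissue, read 7241 on HuFL and 4697 on Hu35K subC, and the selenoprotein SELENOW read 12826 on HuFL. FXYD1, a regulator of the sodium pump, read 8065 on Hu35K subD.

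The zeros on HuFL were not spread evenly, and the tests on them were chosen after they were seen. Probe sets listed at 0 made up 46.9% of those whose identifier starts with X, 39.1% of those with Z, 24.5% of those with Y, 12.4% of those with M and 0.6% of those with HG. Genes listed at 0 on HuFL were above the robust limit on a Hu35K array in 28.0% of cases (exact interval 23.3 to 33.2), against 16.8% (13.3 to 20.7) of genes within 50 of 0. That argues against transcripts too low to measure as the whole cause, but rests on the robust limit, since at 3 noise SD the shares were 7.9% (5.2 to 11.4) and 3.8% (2.2 to 6.2), with overlapping intervals. Genes not at 0 passed the robust limit in 26.5% of cases, so values left out upstream whatever their level may account for the zeros, though no source used here describes such a step.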
